A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

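RNA of untreated and acetic acid-treated cultures of yeast strain BY4741 was compared on 4 two-colour arrays. Total RNA was extracted with acid phenol and labelled indirectly, per the labels' protocols. The authors deposited 1 value per gene and array, taken as the log2 ratio of the channels. Scanner, background correction, normalization within arrays, averaging of spots and the filter that left some genes without a value are not given in the sources used here. The values are signed, have medians near 0 on every array and 3 decimals, as deposited, so they are on a log scale; base 2, the usual base for such arrays, is an assumption. If the base were another, all folds would change, as would the counts at 2-fold and the test against a minimum fold; the other p-values would not. Whether the authors centred the arrays is unknown. Signal intensities were not analysed here, so signal over background is unknown for every gene.

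Groups, dyes and replicate numbers came from the labels: 2 arrays had acid-treated RNA in Cy5 and 2 in Cy3. The direction of the ratios is not stated. By a rule set beforehand, arrays of opposite orientation that all correlated above 0 were taken as already turned the same way by the authors. The ratios were read as treated over untreated, a reading that the turning itself does not settle. Each gene filled 1 line of the table, with 0 duplicated names. Of 5799 systematic gene names, 5336 matched a locus tag of the reference gene table of assembly R64, which gave current symbols and, for a check, lengths, nearly all of the coding sequence alone; 463 kept the name of the table, 24 higher and 5 lower genes among them. No coordinates of that table are printed.

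Values were present on 4 arrays for 4896 genes, on 3 for 395, on 2 for 301 and on 1 for 207. The 5291 genes with at least 3 values were tested and 508 were not. Ratios were fitted with an intercept in limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The shared variance had 3.34 prior degrees of freedom. A second fit had a term for the dye. The design text calls the arrays biological replicates. Same-numbered arrays had a correlation of 0.252 between their deviations from the means of their orientation, and with only 2 such pairs the numbers were not taken to pair the arrays. Whether same-numbered arrays share their RNA is not stated; if they do, n is 2, as in the fit with these arrays averaged.

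There were 29 gene lists, written before the data were examined. They held targets of Haa1, of Msn2/Msn4, of Gcn4, of Aft1/Aft2 and of Pho4, heat shock proteins, transporters and metabolic pathways. Others held cell wall, ribosome, proteasome, histone, cell cycle and proton pump genes. The rest were genes specific to a cells, to alpha cells or to meiosis, and the genes deleted in the strain. For each list the members past the threshold were counted, over all genes and adjusted over the list alone. The 27 lists with enough tested genes were tested against other genes with camera, with a preset correlation of 0.01 and with an estimated one. They were also tested with fry, which asks whether a list moves, on balance, one way and compares it with no other genes. Both were adjusted over lists. None of the calls made with the preset correlation held with an estimated one. The estimated correlation was -0.0138 for oxidative phosphorylation, -0.0131 for oxidative stress and 0.00423 for the tricarboxylic acid cycle, under the preset 0.01. A higher correlation between genes thus did not end the calls of these lists. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays, which it does not with a preset one. For oxidative phosphorylation the unadjusted camera p was 4.69e-09 with the preset correlation and 0.00701 with the estimated one. The loss of these calls thus also reflects the small number of arrays. A further 4 lists were chosen after the data were seen.

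Named genes followed a rule written beforehand. It took the 12 largest increases and 12 largest decreases among genes past the threshold with values of the same sign on 4 arrays. It added up to 4 members per list with the largest change among those past the threshold, or the 2 with the smallest p where no member passed, and the genes deleted in the strain. MDJ1 and HSP12 (as neighbours), MET17 and the dye-following genes are named in addition, as are members of the lists chosen afterwards.

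Alternatives were a term for the dye, the replicate number as a random block, averaging of same-numbered arrays, centring, scaling and quantile normalization of arrays, other minimums of values per gene, robust variance, no shared variance, a minimum fold of 1.5 in limma's treat, and leaving out each array. Removal of a loess trend of each array's ratio on coding length was added after the data were seen. The fit was tested on simulated data of the acid comparison with 5291 genes, 200 of them changed. It recovered 5.22% of genes changed by a log2 ratio of 0.5, 76.3% at 1 and 99.2% at 2, and 6.21% of calls were false. The simulated noise was normal, independent between genes and between arrays, equally wide on every array and without a dye effect. The real arrays differ from this, so these shares do not give the recovery or the false share of the real calls. Figures were drawn with matplotlib 3.10.9.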

Results

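Gene expression was measured in Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a that carries deletions of HIS3, LEU2, MET17 (also called MET15) and URA3. Cultures grew in rich medium (YPD) at 28 °C to an absorbance of 0.6, and 50 ml of culture was exposed to 30 mM acetic acid for 2 h. Each of 4 two-colour arrays carried RNA of an untreated and of an acid-treated culture, one in Cy3 and the other in Cy5. The acid-treated RNA was in Cy5 on 2 arrays and in Cy3 on the other 2. Arrays are named here by the dye of the acid-treated RNA and the replicate number of the labels. The design text describes the 4 arrays as biological replicates, and their number limits the precision of every value. If same-numbered arrays were instead dye swaps of the same RNA, which the labels leave open, n would be 2 rather than 4.

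The table held ratios for 5799 genes, with values for 5484 and 5505 genes on the arrays with acid in Cy5 (replicates 1 and 2) and for 5456 and 5133 genes on those with acid in Cy3. The median log2 ratios of the arrays were 0.0075, 0.01, 0.01 and -0.028 in that order, and the standard deviations 0.70, 0.77, 1.05 and 0.81. Ratios are given as treated over untreated. This direction is likely rather than stated. The study compares treated with untreated cells, and with this reading the targets of the weak-acid factor Haa1, known to rise under weak acids, lie above 0 (14 of 14 tested, median 2.67). The swapped arrays had already been turned the same way, which leaves the direction open. With the opposite reading, every sign below turns. Across genes, which are not independent replicates, all pairs of arrays correlated above 0. Pearson's r was 0.80 between the arrays with acid in Cy5, 0.62 between those with acid in Cy3, and 0.41 to 0.72 between arrays of opposite orientation. The lower values all came from pairs with acid in Cy3 replicate 1. Its r was 0.47 and 0.41 with acid in Cy5 replicates 1 and 2, and 0.62 with acid in Cy3 replicate 2. Acid in Cy3 replicate 2 had 0.67 and 0.72 with acid in Cy5 replicates 1 and 2.

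The comparison of treated with untreated cells addresses how the yeast transcriptome responds to acid stress. Genes of small heat shock proteins, chaperones and the weak-acid response were among the 12 with the largest increases. HSP26, a small heat shock protein, rose by a mean log2 ratio of 6.84 ± 0.71 (SD, n = 4, as for all values below unless stated), or 115-fold. SSA4, a stress-induced member of the Hsp70 family, rose by 6.43 ± 0.81, HSP30, a plasma membrane stress protein, by 5.53 ± 0.72, and YGP1, a secreted cell wall-related glycoprotein, by 5.28 ± 0.90. In the other direction, SIT1, a siderophore iron transporter, fell to a log2 ratio of -3.03 ± 0.74, and GCV2, a subunit of the mitochondrial glycine cleavage complex, to -2.30 ± 0.18.

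The remaining 8 of the 12 largest increases were those of BDH2 (5.87 ± 0.50), PRM7 (5.67 ± 0.38), SPI1 (5.41 ± 1.18), SSE2 (5.35 ± 0.71), YFL015C (5.18 ± 0.73), HSP104 (4.50 ± 0.62), YRO2 (4.48 ± 0.73) and UGA2 (4.40 ± 0.38). HSP104 is a disaggregase, SSE2 an Hsp110-type nucleotide exchange factor, SPI1 a cell wall protein and UGA2 an enzyme of GABA use. YFL015C lies between MDJ1 and HSP12, both of which also rose (1.53 ± 0.12 and 1.96 ± 0.76); whether its spot also takes up signal of a neighbour is not known. SPI1, BDH2 and SSE2 had 1 low array, acid in Cy3 replicate 1, with 3.64, 5.12 and 4.29. Of the 12 largest decreases, 3 belonged to iron uptake (SIT1, FTR1 and FET3) and 3 to purine synthesis, salvage or one-carbon metabolism (GCV2, HPT1 and ADE1). HPT1 fell to -1.22 ± 0.51 and ADE1 to -1.21 ± 0.55. The peptide transporter gene PTR2 fell to -1.38 ± 0.51, the branched-chain amino acid permease gene BAP2 to -1.32 ± 0.22, the uridine permease gene FUI1 to -1.24 ± 0.39 and the mucin-like sensor gene HKR1 to -1.26 ± 0.38. SIZ1, a SUMO ligase gene, and YGR164W fell to -1.59 ± 0.96 and -1.48 ± 0.82; without acid in Cy3 replicate 1 these ratios were -1.11 and -1.08.

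**Figure D1:**
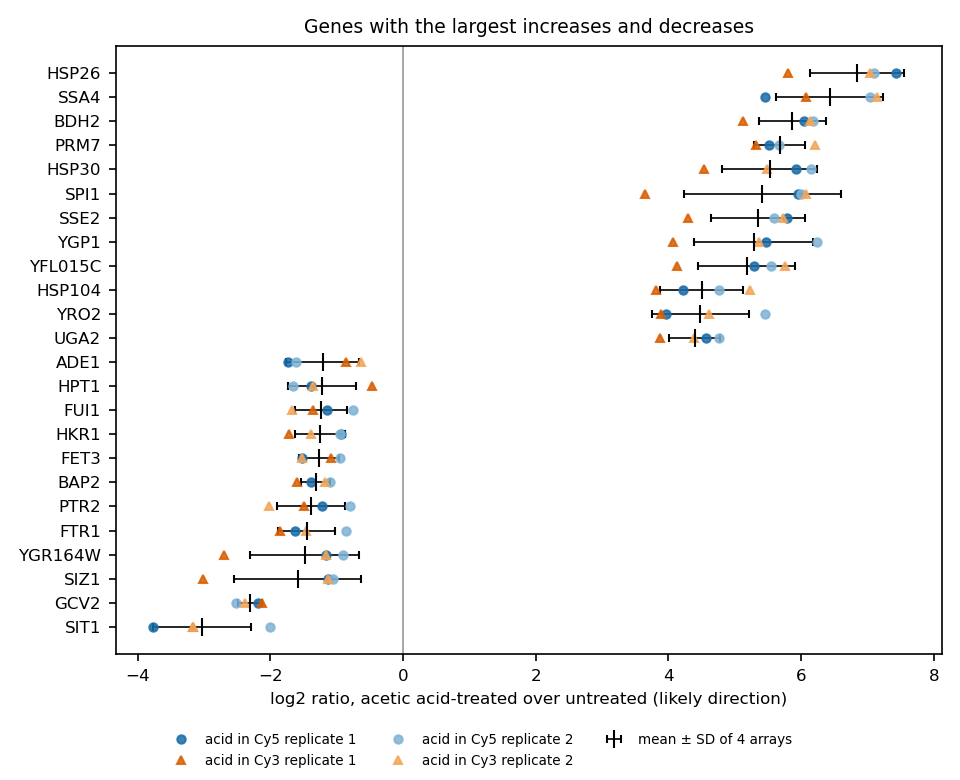
Log2 ratios of acid-treated over untreated RNA (horizontal axis) for the 12 genes with the largest increases and the 12 with the largest decreases. Symbols are single arrays, circles with acid in Cy5 and triangles with acid in Cy3, and bars give the mean ± SD of 4 arrays; SIZ1 and YGR164W have 1 array far below the other 3.

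Of 5291 genes with values on at least 3 arrays, 575 passed an adjusted p of 0.05 in the limma fit: 468 were higher and 107 lower after acetic acid. At least a 2-fold change was fitted for 315 of them, 274 higher and 41 lower, and 40 rose at least 8-fold. All 575 had the same sign on every array that measured them. With so few arrays the threshold all but requires this, so it adds no evidence of agreement beyond the calls. An unadjusted p under 0.05 was reached by 1579 genes. Among the calls, 81.4% were higher, against 66.9% (541 higher, 268 lower) after quantile normalization. With same-numbered arrays averaged, as for dye swaps of the same RNA, 377 genes passed, 306 higher and 71 lower. The number of calls was 271 without acid in Cy5 replicate 1, 251 without acid in Cy5 replicate 2, 197 without acid in Cy3 replicate 2 and 825 without acid in Cy3 replicate 1, with 20, 26, 13 and 221 lower genes in that order. Of 85 named genes past the threshold, 29, 27, 39 and 1 lost their call in these fits.

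Targets of Haa1, the transcription factor of the weak-acid response, had the highest median of all lists, 2.67 over 14 genes tested. Its sign is part of the basis for the direction of the ratios and no separate evidence of it. Of these, 12 rose, none fell and 2 did not pass, with the same counts when adjusted over the list alone. Besides HSP30 and YGP1, YRO2, a membrane protein related to HSP30, rose by 4.48 ± 0.73 and TDA6 by 4.07 ± 0.68. The list stood above other genes in camera with a preset correlation (adjusted p = 1.05e-12), with adjusted p = 0.292 with an estimated correlation. Among targets of the general stress factors Msn2 and Msn4, 23 of 34 rose and none fell (27 higher when adjusted over the list alone). They included SPI1, YGP1, UGA2 and RGI1 (3.57 ± 0.53), a regulator of energy metabolism. The median was 1.09 (camera adjusted p = 1.58e-13; adjusted p = 0.292 with an estimated correlation). Leaving out acid in Cy3 replicate 2 left 10 Haa1 targets and 13 Msn2/Msn4 targets higher, and leaving out acid in Cy5 replicate 2 left 10 and 15.

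Heat shock proteins and chaperones rose in 18 of 23 cases and fell in none (19 higher when adjusted over the list alone), with a median of 1.41. HSP26, SSA4, SSE2 and HSP104 had the largest ratios. The camera test gave an adjusted p of 1.08e-14, and adjusted p = 0.292 with an estimated correlation. Without acid in Cy3 replicate 2, 12 members were higher. Cross-hybridisation between the similar SSA genes, and between HSP82 and HSC82, leaves the ratios of single members of these families uncertain. For trehalose and glycogen metabolism, 3 of 16 genes rose (4 when adjusted over the list alone): the trehalose synthase gene TPS1 by 1.26 ± 0.43, the phosphoglucomutase gene PGM2 by 0.90 ± 0.40 and the glycogen branching gene GLC3 by 0.75 ± 0.21. This list had a median of 0.36 and an adjusted p of 0.0324, against adjusted p = 0.292 with an estimated correlation; without acid in Cy5 replicate 2 or without acid in Cy3 replicate 2, 0 of its genes were called. Its set test did not pass without acid in Cy3 replicate 2 (adjusted p = 0.0796), with a dye term (0.0559), with a minimum of 2 arrays (0.0603) or without shared variance (0.0540). No proteasome subunit of 32 passed, over all genes or when adjusted over the list alone; PRE7 and PRE2, those with the smallest p, had ratios of 0.54 ± 0.14 and 0.52 ± 0.17 (adjusted p = 0.0597 and 0.0687).

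Among oxidative stress genes, 7 of 32 rose and none fell (11 higher when adjusted over the list alone), with a median of 0.40. The NADPH oxidoreductase gene OYE2 rose by 1.44 ± 0.17, the glutathione peroxidase gene GPX2 by 0.99 ± 0.26, the glutathione transferase gene GTT2 by 0.96 ± 0.12 (n = 3) and the peroxiredoxin gene TSA2 by 0.73 ± 0.10. The list had an adjusted p of 0.00132 in camera and adjusted p = 0.292 with an estimated correlation. The number of higher members was 1 without acid in Cy5 replicate 1, without acid in Cy5 replicate 2 or without acid in Cy3 replicate 2.

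Genes of oxidative phosphorylation had a median of 0.51, and 33 of 36 lay above 0. Of these, 10 rose and none fell (17 higher when adjusted over the list alone). CYC7, an isoform of cytochrome c, rose by 3.04 ± 0.10, the complex III subunit genes COR1 and QCR8 by 1.81 ± 0.33 and 1.71 ± 0.16, and the NADH dehydrogenase gene NDE1 by 1.76 ± 0.56. The camera adjusted p was 3.16e-08, and adjusted p = 0.189 with an estimated correlation. In the tricarboxylic acid and glyoxylate cycle list, 6 of 24 rose over all genes tested, against 7 higher and 1 lower when adjusted over the list alone. CIT2, the peroxisomal citrate synthase, rose by 4.34 ± 0.53, its mitochondrial counterpart CIT1 by 1.82 ± 0.27, KGD2 by 1.41 ± 0.32 and IDH2 by 1.19 ± 0.09. The median was 0.22 (adjusted p = 0.0324; adjusted p = 0.292 with an estimated correlation). Without acid in Cy5 replicate 1, acid in Cy5 replicate 2 or acid in Cy3 replicate 2, 6 oxidative phosphorylation genes were called, and without the last of these arrays 4 genes of the cycle. The cycle list did not pass with same-numbered arrays averaged (adjusted p = 0.0511).

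Glycolysis and fermentation genes rose in 8 of 27 cases (11 when adjusted over the list alone), with a median of 0.34. PDC6, a minor pyruvate decarboxylase, rose by 1.65 ± 0.61, ADH5 by 1.42 ± 0.35, the glucose-6-phosphate isomerase gene PGI1 by 1.32 ± 0.41 and the phosphoglycerate mutase gene GPM1 by 1.24 ± 0.14. Camera gave an adjusted p of 0.00889, and adjusted p = 0.746 with an estimated correlation. Without acid in Cy3 replicate 2, 2 members were called and the list did not pass (median 0.23, adjusted p = 0.0963), as with fry (adjusted p = 0.0890); without acid in Cy5 replicate 2, 4 members were called. Hexose transporter genes rose in 4 of 12 cases (6 when adjusted over the list alone): HXT4 by 2.79 ± 0.52, HXT3 by 2.50 ± 0.71, HXT7 by 1.90 ± 0.79 and HXT1 by 1.43 ± 0.72. HXT7 is nearly identical to HXT6, so its signal is uncertain. This list had a median of 0.68 (adjusted p = 0.0262; adjusted p = 0.666 with an estimated correlation), and 2 members were called without acid in Cy5 replicate 1 or without acid in Cy3 replicate 2. It did not pass without acid in Cy5 replicate 1 (adjusted p = 0.0689), without acid in Cy5 replicate 2 (0.0624) or with fry (0.0807).

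In sulfur and methionine metabolism 11 of 24 genes rose and none fell (13 higher when adjusted over the list alone), with a median of 0.53. MET16 and MET14, of sulfate assimilation, rose by 1.76 ± 0.22 and 1.27 ± 0.33, and the S-adenosylmethionine permease gene SAM3 and the methionine permease gene MUP3 by 1.49 ± 0.60 and 1.25 ± 0.66. The list had an adjusted p of 3.35e-05, and adjusted p = 0.292 with an estimated correlation. Only 2, 4 and 1 members were called without acid in Cy5 replicate 1, acid in Cy5 replicate 2 and acid in Cy3 replicate 2. Of 54 amino acid synthesis genes under Gcn4, 10 rose over all genes tested, against 11 higher and 1 lower when adjusted over the list alone. TRP5 rose by 1.75 ± 0.43, LEU1 by 1.61 ± 0.83, HOM3 by 1.41 ± 0.20 and ARG1 by 1.31 ± 0.17. The median was 0.19 (adjusted p = 0.0103; adjusted p = 0.666 with an estimated correlation), and 5 and 4 members were called without acid in Cy5 replicate 2 and acid in Cy3 replicate 2. With fry this list did not pass (adjusted p = 0.0560).

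Members of the iron regulon moved in both directions. SIT1 fell as above, the high-affinity permease gene FTR1 to -1.46 ± 0.43 and the ferroxidase gene FET3 to -1.27 ± 0.30, while ISU1, a scaffold for iron-sulfur cluster assembly, rose by 2.39 ± 0.64. Of 22 genes 4 fell and 2 rose, with the same counts when adjusted over the list alone. Only 1 was higher without acid in Cy5 replicate 1, acid in Cy5 replicate 2 or acid in Cy3 replicate 2, with 4, 4 and 3 lower. The list as a whole had a median of -0.07 and did not pass (adjusted p = 0.246); without acid in Cy5 replicate 2, where its median was 0.25, the median was -0.23 and the adjusted p 0.0378. Among 27 permease and nitrogen catabolite genes, 4 rose and 2 fell, also when adjusted over the list alone. UGA1, of GABA use, rose by 2.79 ± 0.50 and PUT1, of proline use, by 2.63 ± 1.17; PTR2 and BAP2 fell. The median was -0.08, the mean 0.07 and the adjusted p 0.790. In the phosphate regulon PHM8 rose by 2.54 ± 0.14 and the acid phosphatase gene PHO5 by 0.88 ± 0.45, and VTC3 fell to -0.84 ± 0.37, among 16 genes (2 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.641). PHM8 is also an Haa1 target. Without acid in Cy3 replicate 2, 1 permease or nitrogen gene was higher and 1 lower, and 1 phosphate gene was called.

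Cell wall genes rose in 12 of 36 cases and fell in 2, against 12 and 3 when adjusted over the list alone. Besides SPI1, the yapsin protease gene YPS3 rose by 3.79 ± 0.28, PST1 by 2.67 ± 0.68 and NCW2 by 1.81 ± 0.22. The median was 0.25 (adjusted p = 0.0103; adjusted p = 0.746 with an estimated correlation), and 7 members were higher without acid in Cy3 replicate 2. The list did not pass without acid in Cy5 replicate 2 (median 0.0737, adjusted p = 0.0624) or with fry (adjusted p = 0.0560). Of 20 weak-acid and drug transporter genes, 5 rose and 1 fell (5 and 2 when adjusted over the list alone). PDR12, the weak-acid exporter, rose by 2.49 ± 0.71, AQR1 by 2.34 ± 0.60 and TPO4 by 0.93 ± 0.47, and the multidrug transporter gene PDR5 fell to -1.20 ± 0.46, with -0.51 on acid in Cy5 replicate 2. The list's median was -0.09 but its mean 0.16, and it did not pass (adjusted p = 0.747). Without acid in Cy5 replicate 1, acid in Cy5 replicate 2 or acid in Cy3 replicate 2, 2 of its members were higher. In plasma membrane ion transport, 3 of 13 rose and 2 fell (4 and 2 when adjusted over the list alone). The kinase genes HAL5 and SAT4 rose by 2.14 ± 0.17 and 0.83 ± 0.21, and the potassium transporter gene TRK1 and the sodium pump gene ENA2 fell to -0.75 ± 0.26 and -0.94 ± 0.47. ENA2 has near-identical copies. The list had a median of -0.05, a mean of 0.22 and an adjusted p of 0.564, and 1 member was called without acid in Cy3 replicate 2. No gene of the vacuolar proton pump passed among 18, also when adjusted over the list alone. RAV1 and VMA11 had ratios of -0.50 ± 0.09 and -0.60 ± 0.51 (adjusted p = 0.0642 and 0.131), and the list a median of -0.18 and an adjusted p of 0.182.

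Of 129 genes of cytosolic ribosomal proteins, 103 lay below 0 and 26 above, but 0 passed, over all genes or when adjusted over the list alone. The median was -0.24, with an adjusted p of 1.23e-05 in camera and adjusted p = 0.625 with an estimated correlation; with fry it did not pass (adjusted p = 0.0708). RPS22A (-0.61 ± 0.21) and RPS1A (0.64 ± 0.29) had the smallest p (adjusted p = 0.0509 and 0.0593), and both have near-identical copies. Without acid in Cy3 replicate 1, 7 members were lower and 1 higher. Among 92 ribosome biogenesis factors 3 rose, and 2 when adjusted over the list alone: NOP1, the fibrillarin gene, by 2.69 ± 0.23, UTP30 by 1.02 ± 0.24 and DBP3 by 0.99 ± 0.46. The median was 0.10 (adjusted p = 0.573), and 1 factor was called without acid in Cy3 replicate 2. None of 19 subunits of RNA polymerases I and III passed, also when adjusted over the list alone. RPO31 and RET1 had ratios of -0.70 ± 0.41 and -0.65 ± 0.46 (adjusted p = 0.0704 and 0.0969), with a list median of -0.04 and an adjusted p of 0.641.

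Among 10 histone genes 9 lay below 0, with a median of -0.35, though 0 passed, over all genes or when adjusted over the list alone. The list had an adjusted p of 0.0163, and adjusted p = 0.666 with an estimated correlation. Without acid in Cy3 replicate 1, 3 histone genes were lower, and 1 after quantile normalization. The list did not pass without acid in Cy5 replicate 2 (median -0.27, adjusted p = 0.0624) or with fry (adjusted p = 0.0958). HTB2 and HHF1 had ratios of -0.59 ± 0.28 and -0.55 ± 0.36 (adjusted p = 0.0690 and 0.102), and both have near-identical copies. Of 31 cell cycle genes, PCL9 rose by 0.69 ± 0.23, and WHI5, a repressor of the G1/S transition, and the DNA polymerase gene POL1 fell to -0.98 ± 0.46 and -0.80 ± 0.37, with the same counts when adjusted over the list alone (median -0.10, adjusted p = 0.564). In ergosterol synthesis ERG9 rose by 0.70 ± 0.27, and HMG1 and ERG2 fell to -0.93 ± 0.42 and -0.81 ± 0.40, among 27 genes (2 higher and 2 lower when adjusted over the list alone; median 0.17, mean 0.04, adjusted p = 0.653). Without acid in Cy5 replicate 1, acid in Cy5 replicate 2 or acid in Cy3 replicate 2, 0 genes of the cell cycle and ergosterol lists were called.

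The lists for alpha cells, for meiosis and for the deleted genes served as checks, while genes specific to a cells belong to this strain's own mating type. Of 5 genes specific to a cells, STE6, the a-factor exporter, fell to -0.94 ± 0.34. It also passed when adjusted over the list alone (list median -0.25, list adjusted p = 0.564). The 2 alpha-specific genes tested, SAG1 and MF(ALPHA)2, had ratios of -0.20 ± 0.59 and -0.20 ± 0.24 and did not pass, also when adjusted over the list alone. Among 20 meiosis and sporulation genes only SPS2 rose, by 0.62 ± 0.09, and 0 when adjusted over the list alone (median -0.06, list adjusted p = 0.840). The calls of STE6 and SPS2 were lost without acid in Cy3 replicate 2 or acid in Cy5 replicate 1, and that of SPS2 also without acid in Cy5 replicate 2. Of the genes deleted in the strain, HIS3 and URA3 had ratios of -0.03 ± 0.52 and -0.70 ± 0.83 and did not pass (adjusted p = 0.933 and 0.188), also when adjusted over the list alone. MET17 had values on 2 arrays, 0.12 on acid in Cy5 replicate 1 and -2.58 on acid in Cy3 replicate 1, and was not tested. LEU2 was not analysed here. URA3 was also lowest on acid in Cy3 replicate 1, at -1.94. Since MET17 and URA3 are deleted, ratios this low on that array can arise without a change of the gene's transcript. The lowest values of SIZ1 (-3.02) and YGR164W (-2.70) came from the same array.

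**Figure D2:**
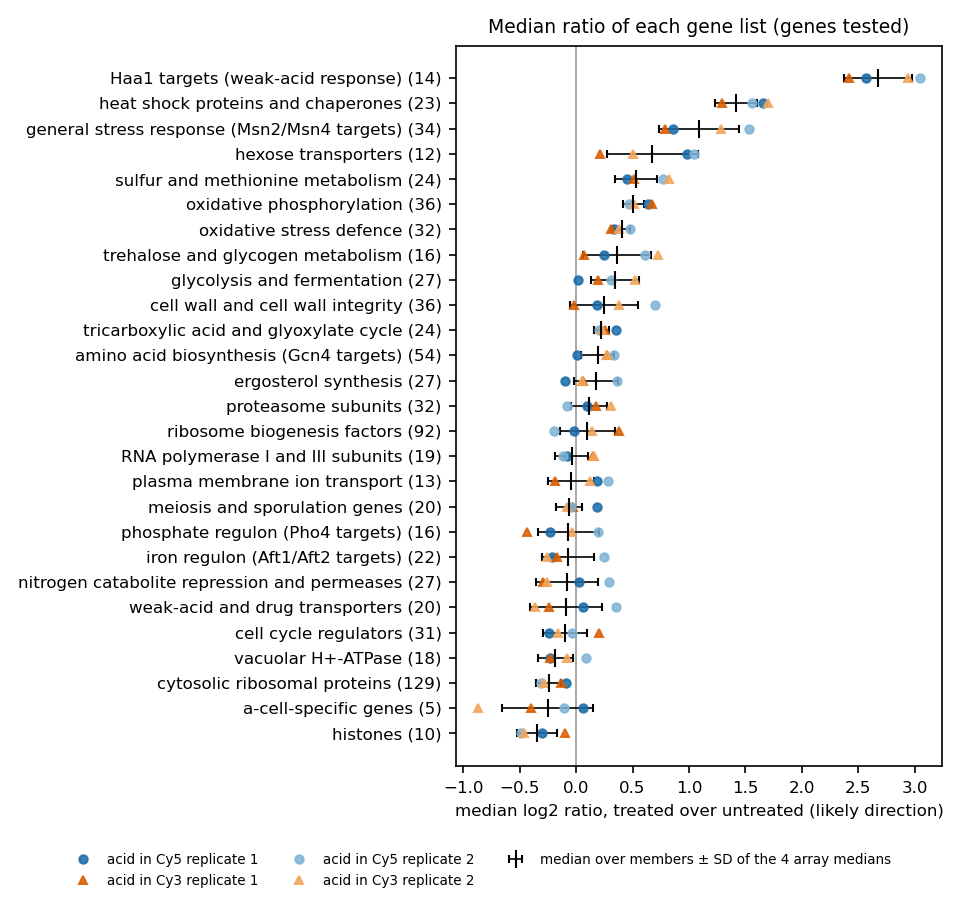
Median log2 ratio of acid-treated over untreated RNA (horizontal axis) over the tested members of each gene list with at least 3, with their number in brackets. Symbols are the medians of single arrays, and bars give the list median ± SD of the 4 array medians; of the 27 lists drawn, Haa1 targets lie highest (2.67) and histones lowest (-0.35).

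Removing a trend with coding length, an alternative chosen after the data were seen, left 58 of the 102 lower calls with a length and 388 of the 444 higher ones, among 87 lower and 405 higher calls. It ended the calls of TRK1, POL1, HMG1, STE6, ENA2 and SIZ1 among the named lower genes, with ratios from -1.45 (SIZ1) to -0.44 (POL1). It also ended those of PHO5, ERG9, PCL9 and SPS2 among the named higher genes, with ratios of 0.74, 0.57, 0.65 and 0.48. The set tests of amino acid synthesis, the tricarboxylic acid cycle, hexose transporters and histones also ended, with adjusted p = 0.0582, 0.0601, 0.0601 and 0.0582.

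The dye swaps allowed the effect of the dye to be separated from that of the acid. A ratio that followed the dye was found for 12 genes in the limma fit, and 372 had an unadjusted p under 0.05. All 12 had higher ratios with acid in Cy5 than with acid in Cy3, and 0 of them passed the test for acid. That test had no dye term, so their difference between orientations counted as noise. The 0 thus says nothing about an effect of acid on these genes. POP6, a subunit of ribonuclease P and MRP, had a mean log2 ratio of 4.68 with acid in Cy5 and -6.30 with acid in Cy3. JAC1, a co-chaperone of iron-sulfur cluster assembly, had 4.28 and -5.84. The count was 66 without acid in Cy3 replicate 1 and 904 without acid in Cy3 replicate 2, where the remaining single array with acid in Cy3 is taken to vary like the other 2.

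**Figure D3:**
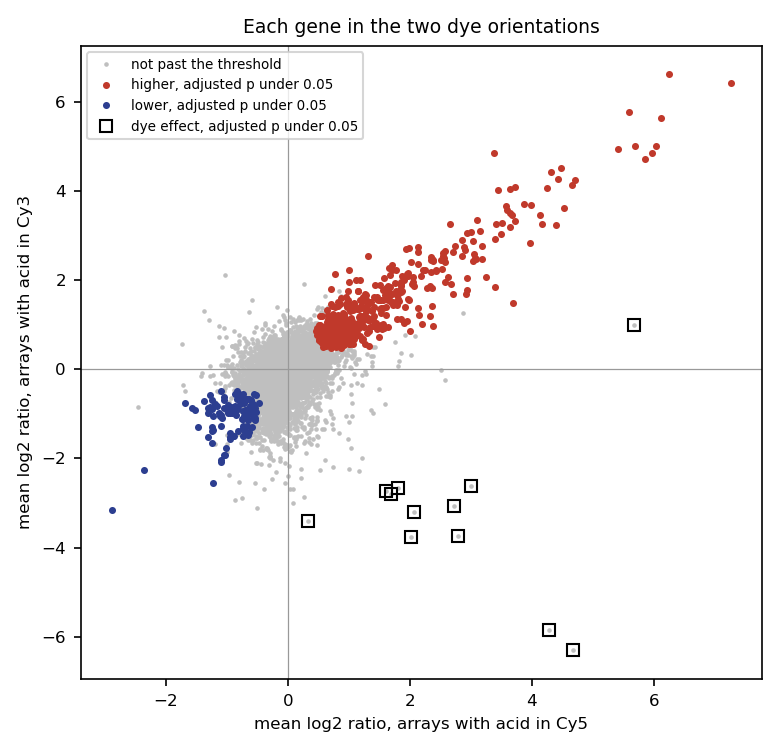
Mean log2 ratio of acid-treated over untreated RNA for each gene on the arrays with acid in Cy5 (horizontal axis) and with acid in Cy3 (vertical axis). Red and blue points are the 468 higher and 107 lower genes, and squares are genes whose ratio followed the dye, which have a higher ratio with acid in Cy5.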

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

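The tests of why ratios followed the dye were chosen after that pattern was seen. For 8 of the 127 named genes and list medians with 4 arrays, 1 array lay far from the other 3 by Dixon's test, which chance gives in about 1 of 20. On acid in Cy3 replicate 1, BDH2 had a log2 ratio of 5.12 (others 6.05 to 6.17), SPI1 3.64 (5.95 to 6.08), SSE2 4.29 (5.59 to 5.79), URA3 -1.94 (-0.39 to -0.16), YGR164W -2.70 (-1.17 to -0.91) and SIZ1 -3.02 (-1.14 to -1.05). On acid in Cy5 replicate 2, PDR5 had -0.51 (-1.52 to -1.36) and the iron regulon a median of 0.25 (-0.26 to -0.17).

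Ratios differed between the dye orientations, by the dye term of the limma fit, for 12 genes. The differences in log2 ratio, acid in Cy5 minus acid in Cy3, were 10.98 for POP6, 10.12 for JAC1, 6.52 for SOH1, 5.80 for SUE1, 5.79 for YGL118C, 5.62 for BIL2, 5.26 for MPO1, 4.68 for BSC1, 4.50 for YGR045C, 4.47 for BRP1, 4.34 for RTS2 and 3.74 for ADR1.

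Whether one array alone gives rise to some of these differences stays open. For 9 of the 12 genes both arrays of one orientation lay above both of the other, but the dye term by which they were selected favours such genes. Spots handled together (neighbouring ORFs share array or plate positions) remain a candidate explanation: 8 of the 12 genes lie on chromosome VII, which holds 9.58% of the genes tested. The 95% interval of random draws of 12 genes reached up to 5 on one chromosome, and a share of 1e-04, the smallest the draws can give, reached 8. Positions on the array were not analysed here, so this stays a hypothesis. No biological explanation was tested, since acid and dye were balanced by design.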

How the results depend on the processing

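Removal of the length trend was chosen after the data were seen. Of the 85 named genes past the threshold, 33 stayed past it in the same direction under all 15 other settings, 45 under all except the fit without shared variance, and 0 reversed with a call. Calls numbered 575 (468 higher, 107 lower), but 377 (306 and 71) with same-numbered arrays averaged and 204 (188 and 16) without shared variance. Not all of these were calls of the main fit: 292 higher and 54 lower were shared with averaging, and 141 and 10 without shared variance. Lower calls numbered 207 with a dye term, 189 after scaling and 268 after quantile normalization. With the replicate number as a block there were 733 calls, 176 of them lower, at a block correlation of -0.109. That fit had no dye term, and same-numbered arrays have opposite dyes, so differences between the orientations can lower this correlation. Deviations of same-numbered arrays from the orientation means correlated at 0.252. A block correlation under 0 narrows the standard errors, so the higher count is no sign that same-numbered arrays are independent. At least 2-fold calls (315) numbered 111 without shared variance and 168 with treat. Dye calls (12) numbered 0 without shared variance and 7 with the length trend removed. With all signs turned, 18.6% of calls were higher. Leaving out single arrays gave 197 (without acid in Cy3 replicate 2) to 825 calls (without acid in Cy3 replicate 1), 184 to 604 higher, 13 to 221 lower, 197 to 339 at least 2-fold and 9 to 904 for the dye. List medians do not depend on the set test. With an estimated correlation the adjusted p was 0.292 for Haa1 targets (2.67), general stress (1.09), heat shock proteins (1.41), trehalose (0.36), sulfur (0.53), the tricarboxylic acid cycle (0.22) and oxidative stress (0.40), 0.189 for oxidative phosphorylation (0.51), 0.625 for ribosomal proteins (-0.24), 0.666 for amino acids (0.19), hexose transporters (0.68) and histones (-0.35), and 0.746 for cell wall (0.25) and glycolysis (0.34). With fry, which tests whether a list moves one way, ribosomal proteins (-0.24, adjusted p = 0.0708), amino acids (0.19, 0.0560), cell wall (0.25, 0.0560), glycolysis (0.34, 0.0890), hexose transporters (0.68, 0.0807) and histones (-0.35, 0.0958) did not pass. Haa1 targets (adjusted p = 0.00400), general stress (0.00993), heat shock proteins (0.00266) and trehalose (0.0237) passed with fry. So did sulfur (0.0312), oxidative phosphorylation (0.00266), the tricarboxylic acid cycle (0.00993) and oxidative stress (0.00400). The trehalose call ended with a dye term (0.38), with a minimum of 2 arrays (0.34) and without shared variance (0.36), and that of the tricarboxylic acid cycle with same-numbered arrays averaged (0.22). Calls of amino acids (0.11), the tricarboxylic acid cycle (0.17), hexose transporters (0.57) and histones (-0.27) ended with the length trend removed. Leaving out single arrays gave medians of 0.36 to 0.50 for trehalose (call lost without acid in Cy3 replicate 2), 0.0737 to 0.376 for cell wall (lost without acid in Cy5 replicate 2), 0.23 to 0.40 for glycolysis (lost without acid in Cy3 replicate 2), 0.53 to 0.87 for hexose transporters (lost without acid in Cy5 replicate 1 or 2), -0.45 to -0.27 for histones (lost without acid in Cy5 replicate 2) and -0.227 to -0.006 for iron (call gained without acid in Cy5 replicate 2). Fewer arrays or no shared variance leave fewer degrees of freedom, but this would not raise the calls to 825 without acid in Cy3 replicate 1. Acid in Cy3 replicate 1 had the widest ratios, with an interquartile range of 1.11. It was 0.605 and 0.693 on acid in Cy5 replicates 1 and 2, and 0.715 on acid in Cy3 replicate 2. Acid in Cy3 replicate 1 also correlated least with the other arrays. Whether its spread caused that rise was not tested, nor was the cause of the other changes. Testing each probe on its own was not run, since each gene had 1 line. Signal over background was not analysed here.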

Other observations

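The lists in the next paragraph were chosen after the data were seen, as were the tests of a smooth trend with coding length and of a dye effect growing with length, and the counts by orientation and without acid in Cy5 replicate 1.

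Genes of purine synthesis and one-carbon metabolism fell in 10 of 25 cases and rose in none, with a median log2 ratio of -0.82. GCV2 fell to -2.30 ± 0.18, MTD1 to -1.21 ± 0.65, ADE6 to -1.14 ± 0.31 and GCV3 to -1.13 ± 0.38 (SD, n = 4). The camera adjusted p was 5.46e-06, with p = 0.126 with an estimated correlation, and 13 members were lower with the length trend removed. In a list of the Arp2/3 complex and actin patches, 7 of 23 rose and none fell, with a median of 0.41. The fimbrin gene SAC6 rose by 1.96 ± 0.48, RVS161 by 1.40 ± 0.37 and ARP2 by 0.89 ± 0.28 (adjusted p = 0.00904; p = 0.0847 with an estimated correlation). Genes of SMC complexes, which hold and fold chromosomes, fell in 4 of 17 cases and rose in 1, KRE29 (1.31 ± 0.11), with a median of -0.50 (adjusted p = 0.0103; p = 0.0766 with an estimated correlation). SMC6 fell to -1.32 ± 0.25 (n = 3) and SMC1 to -1.07 ± 0.47, but with the length trend removed 1 member was lower and the adjusted p was 0.0501. Of 8 genes of the GABA shunt and proline use, 5 rose: UGA2 by 4.40 ± 0.38, UGA1 by 2.79 ± 0.50, PUT1 by 2.63 ± 1.17, GAD1 by 1.75 ± 0.58 and PUT2 by 0.65 ± 0.22. The median was 1.20 (adjusted p = 0.000720; p = 0.122 with an estimated correlation). These lists were drawn up from the called genes, so their tests are no independent evidence.

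The direction of the ratios was tested with the Haa1 list, whose targets are known to rise under weak acids. The opposite reading, untreated over treated, predicted a median under 0, and the median was 2.67 with 14 of 14 genes above 0. This argues against the opposite reading, as far as that knowledge holds in this strain and medium. The number of calls was also counted under other signs of the arrays: of the 8 sign patterns, 1 gave as many as 575, the real one, and the highest other gave 3. With 8 patterns the share cannot go under 0.05.

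Lower calls gathered among long genes: of 102 with a coding length in the reference table, 61 were 2019 bp or longer (the fifth of genes that is longest), where random draws gave up to 28 in their 95% interval and 45 of 444 higher calls were as long. Without acid in Cy3 replicate 1, 51.0% of lower calls were still as long, which argues against that array as the carrier. Without acid in Cy5 replicate 1, 7 of 19 were, with no chance range drawn. On that array the median of long genes minus that of others was -0.392, against -0.164 on acid in Cy5 replicate 2. It was -0.182 and -0.124 on acid in Cy3 replicates 1 and 2. Each value lay below the interval of random draws, and how much of the pattern acid in Cy5 replicate 1 carries stays open. A dye effect growing with length, acting alone, would turn its sign with acid in Cy3 and cancel in the balanced mean. Over all genes with 4 values, called or not, the median of these long genes minus that of the others was averaged by orientation. It was -0.15 ± 0.04 (SD, n = 2) with acid in Cy3 and -0.28 ± 0.16 with acid in Cy5. This argues against a dye effect as the only source, but leaves open a dye part on top of another trend. Of the 102 lowest genes on the arrays of one orientation alone, 63 were as long with acid in Cy5 and 26 with acid in Cy3, where chance gives 12 to 28. A smooth trend of the ratio with length, whatever its source, may account for part of the pattern. Once it was removed, 18 of 87 lower calls were as long, with up to 25 by chance. Of the 102 earlier lower calls, 58 stayed lower, 18 of the 61 long ones among them. Removal brings the long genes near the level of the others whether the trend is technical or biological. The fall in their count was thus largely set by the removal and says nothing about the source. The median of the 61 genes moved from -0.91 to -0.68 (SD over genes 0.30 and 0.32). These genes were chosen as lower calls, whereas all tested genes of 2019 bp or longer had a median log2 ratio of -0.205. Removing a trend of that size would leave genes chosen in this way low, whatever the source, so their median decides nothing about it. The trend, from labelling or RNA quality for example, cannot be told apart from a lower level of long transcripts in acid-treated cells. That alternative was not tested.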
